A study of Mus musculus with 20 samples.

How the data were processed

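Whole blood of 4 female C57Bl/6 mice was sampled before (day 0) and 10, 15, 20 and 25 days after subcutaneous inoculation with Hepa1-6 cells, a mouse hepatoma line. The labels' protocols state that blood was kept in RNAlater, that RNA was extracted with the RiboPure-Blood kit and that it was labelled with the QuickAmp kit. Each of the 20 arrays, a whole mouse genome design of Agilent, held 1 mouse sample in Cy5 and a common reference of untreated C57Bl/6 blood in Cy3, per the labels, so that a ratio above 0 means a higher level in the mouse sample. Dyes were not swapped, and dye effects that are the same on all arrays cancel between days. The labels give the mouse number and the day of every array, which set the groups. The mouse numbers also pair the samples, since each mouse was bled on all 5 days. Deviations from the day means correlated at a mean r across genes of 0.0872 over the 40 pairs of arrays of 1 mouse (21 of them above 0.1, range -0.422 to 0.540) and at -0.0296 over the 120 pairs of different mice, and duplicateCorrelation gave 0.0372.

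The deposited scanner files hold intensity values, per the file headers the mean signal and the median local background of each spot in both channels, as written by Agilent Feature Extraction 9.1.3.1. Per the file headers that software also computed a processed signal with spatial detrending and linear and lowess dye normalization, from which the deposited log10 ratio of red over green was made. The deposited series matrix table held the same log10 ratio for 900360 of 900360 values (100%, equal to within 1e-6), with a median of 0 in every column, so its scale, centring and direction are known. Further processing by the authors is not given in the sources used here. The mean and background intensity of each channel, deposited without normalization, were the start of all main values here, and the log10 ratios, multiplied to the log2 scale, served only as alternatives.

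Background was corrected with normexp (offset 50, fitted on all spots) and each array was normalized by loess, with control spots at weight 0, in limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table). No scaling between arrays was applied. Control spots (1486 positive or structural and 153 negative) and spots marked non-uniform in either channel (9 to 214 per array) were left out, and spots of the same probe were averaged. A probe was kept if its Cy5 signal was well above background on at least 4 of 20 arrays and if it was measured on at least 3 arrays of every day, which left 20920 probes. For genes with several probes (4337) the probe with the highest mean brightness stood for the gene, which left 15161 genes. Different probes of a gene changed in opposite directions in 14, 5, 0, 0 and 99 genes of the 5 comparisons, in the order days 10, 15, 20 and 25 against day 0 and day 25 against day 10. Names came from a table of mouse genes of the assembly GRCm38.p6, used for names only. Of 41174 probes 23374 (56.8%) matched by accession, 6733 (16.4%) by symbol and 2919 (7.09%) by synonym, and 8148 (19.8%) kept the name in the file. Coordinates are not used here. Probes of immunoglobulin, T cell receptor, histone, haemoglobin and H2 genes are uncertain between near-identical copies.

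Log2(Cy5/Cy3) values of all 20 arrays entered 1 limma fit (lmFit, eBayes) with 5 day means and no block. The 4 later days were each compared with day 0, day 25 was compared with day 10, and an F test covered the 4 comparisons with day 0. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. A gene not well above background on any array of a day has only a bound there, given as "at least N-fold": the mean of the other day, per channel after loess and Aquantile, over the higher of the lowest signal well above background and the gene's own. Such bounds are open to dye bias. The number of arrays limits the precision, and values of probes near background are limited by their signal.

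Gene lists were written for cell types of blood (mature neutrophil, granule proteins of immature granulocytes, myeloid suppressor associated, monocyte, B cell, plasma cell, T cell, cytotoxic and NK cell, regulatory T cell and checkpoint, erythroid, platelet, eosinophil and basophil, dendritic cell, haematopoietic progenitor), for functions (heme synthesis and iron, MHC class II, MHC class I presentation, interferon stimulated, inflammatory cytokine and NF-kB, phagocyte receptors and oxidase, cell cycle, ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, immediate early, heat shock and unfolded protein) and for other tissues (liver and hepatoma, skin and muscle). These 28 lists were tested with camera at its preset correlation of 0.01, adjusted over all lists and all 5 comparisons, with camera at an estimated correlation and fry beside it. Members past the threshold are counted over all genes tested and also adjusted over the list alone. The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 highest and 8 lowest log2 changes among genes past the threshold with the same sign in all mice and a gene symbol that is not a clone name, accession or similar placeholder (which leaves out BC089618), up to 4 members with the smallest p in each list described (2 where more than 6 lists shifted, a limit set after the values were seen), members past the threshold against the rest of their list, and at every day Arg1, Il1b, S100a8, S100a9, Cd79a, Cd3e, Alas2, Pf4, Afp and Alb. Results of 4 genes that this rule takes are not reported here.

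The alternatives fixed in advance were mouse as a fixed or random block, no background correction, an offset of 0, the scanner software's log ratio, the series matrix, centring on the median in place of loess, Aquantile or scale normalization between arrays, the Cy5 channel alone with quantile normalization, no filter on dim probes, a filter on all 20 arrays, non-uniform spots kept, every probe tested, eBayes with trend and robust, array weights, only the arrays of the days compared, a 2-fold minimum, and each mouse or array left out. Chosen after seeing the data were the negative control spots as background, both channels well above background on all 20 arrays, leaving out the arrays of mouse 320 on day 0 and mouse 305 on day 20, and the comparisons among days 15, 20 and 25. The comparison of the erythroid list with the spike-in probes, and of sign changes with the median of all genes, was also chosen then. The first of these settings was redefined once. In its first form it passed through normexp, which removes a constant shift, and changed nothing, so the negative control median and the local background were then subtracted, values under 0.5 were set to 0.5 and 50 was added.

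The arrays of each day lay on 1 slide, so slide could not be fitted. Position on it went with the mouse, a block tried above. Days 15, 20 and 25 shared a scan date, while days 0 and 10 each had their own. The fit was tested on simulated data with 200 of 15161 genes changed. Over the 5 comparisons it recovered 83.6% to 91.0% of genes changed 1.5-fold, 92.5% to 98.5% at 2-fold and 98.5% to 100% at 4-fold. Of calls, 2.66% to 8.21% were false. A shift of 0.5 in the B cell list was called in all 5, with 0 or 1 other list. Splits of the real arrays called up to 13 lists, so these rates may be too low. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.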

Results

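Blood was drawn from 4 female C57Bl/6 mice, numbered 305, 310, 315 and 320, before they received Hepa1-6 cells under the skin and again 10, 15, 20 and 25 days later. Hepa1-6 is a mouse hepatoma line. Each of the 20 blood samples was hybridised, labelled with Cy5, on a whole-genome Agilent array beside a common reference of untreated C57Bl/6 blood labelled with Cy3. The series compared blood before and after inoculation. Each array held 45018 spots, of which between 38.1% and 52.2% were well above background in the Cy5 channel, and the number of arrays limits the precision of every value below. The median Cy5 net intensity was between 50.1 and 69.6 on day 0, between 17.0 and 21.1 on day 10, at most 16.4 on day 15, between 13.3 and 16.8 on day 20 and between 21.9 and 29.7 on day 25. The 4 arrays of a day lay on 1 slide, so a difference between days cannot be told apart from a difference between slides, and no arrays of mice without tumour cells on the later days were analysed here. Changes are differences in log2(Cy5/Cy3) with standard errors from the fit over all 20 arrays, with n = 4 mice per day. Of the genes named, 1 array lacked a value for Hba-a1 on days 0, 15 and 20, for Glrx5, Pf4 and Psme2 on day 0, for Tapbp on day 10, for Oaz1 and Rps27 on day 15 and for Junb and Rpl28 on day 25, which left n = 3.

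Of 15161 genes tested with limma, 4695 differed among the 5 days (F test, adjusted p under 0.05). At all 4 bleeds after inoculation 9 genes were lower than at day 0 and 0 were higher, with S100a8 and S100a9 among the lower. S100a9, which forms calprotectin with S100a8, changed by -2.03, -2.10, -2.52 and -1.42 at days 10, 15, 20 and 25 (SE 0.27), and S100a8 by -1.83, -1.59, -2.09 and -1.19 (SE 0.23). Adam8, a membrane metalloprotease of granulocytes, changed by -1.10, -1.17, -1.23 and -0.81 (SE 0.13), and Socs3, a feedback inhibitor of cytokine signalling, by -0.64, -0.80, -0.68 and -0.79 (SE 0.14). Slc16a3, a lactate exporter, changed by -0.59, -0.80, -0.68 and -0.66 (SE 0.13), and Gsr, glutathione reductase, by -0.72, -0.85, -0.85 and -0.65 (SE 0.11). Wfdc21 changed by -0.98 to -1.32 (SE 0.16), BC089618 by -1.74 to -2.31 (SE 0.28) and Txnl1 by -0.24 to -0.43 (SE 0.076). S100a9 at day 25 and Txnl1 at day 10 were lower in 3 of 4 mice, and the other values were lower in all 4. Gsr, Txnl1 and BC089618, the last for its accession-like name, fall outside the rule for named genes and were chosen after their values were seen. The highest and lowest genes named below are those with a gene symbol. At days 10, 15 and 20 alike 93 genes were higher and 207 lower (22 to 36 and 41 to 68 with the day 0 arrays split). The 4 comparisons share the day 0 arrays. Unchanged days simulated against those arrays gave 0 shared genes in 100 draws, and independent lists of the observed sizes would share 0.00297 lower genes. Both may be too low, as some splits of arrays called up to 1578 genes. With the day 0 arrays split the count was 0 to 13. Without 1 array the count of 9 became 20 (mouse 305, day 0), 1 (310, day 0), 5 (320, day 10), 5 (305 or 315, day 15), 5 (305 or 320, day 20), 3 (305, day 25), 38 (310, day 25), 4 (315, day 25), 1 (320, day 25) or 0 (320, day 0; limma, with 192 genes at an unadjusted p under 0.05 in all 4 comparisons). With mouse as a block it was 22.

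**Figure D1:**
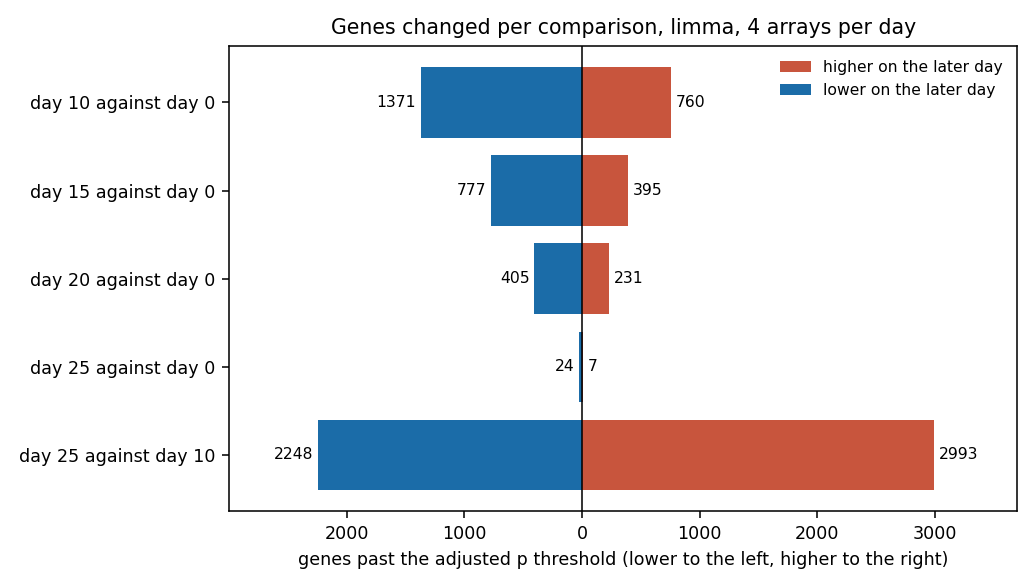
Number of genes (horizontal axis) past an adjusted p of 0.05 in each comparison (vertical axis), out of 15161 tested on 20 arrays of 4 mice. Bars run to the right of 0 for higher genes and to the left for lower genes. Day 10 against day 0 gave 760 higher and 1371 lower genes, day 25 against day 0 gave 7 and 24, and day 25 against day 10 gave 2993 and 2248.

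Against day 0, the blood of day 10 held lower levels of mature neutrophil transcripts. Of the 18 neutrophil list genes kept, 12 were lower, 0 higher and 6 not past the threshold, and 13 were lower when adjusted over the list alone. The list mean was -0.73, below 0 in 4 of 4 mice (adjusted p = 1.90e-08 by camera and adjusted p = 0.465 with an estimated correlation). S100a9 changed by -2.03 (adjusted p = 0.000744) and S100a8 by -1.83 (adjusted p = 0.000551), while Slpi, a protease inhibitor, changed by -0.98 (SE 0.16) and Mmp8, the neutrophil collagenase, by -0.87 (SE 0.17). The other 6 of the 8 lowest genes with a symbol were Cebpd, a transcription factor of granulocytes (-1.45, SE 0.22), Cd300lf, an inhibitory receptor of myeloid cells (-1.38, SE 0.19; its other probe gave -0.17), Il1b (-1.36, SE 0.26), Hp, which codes for haptoglobin (-1.29, SE 0.24), Lrg1 (-1.22, SE 0.28) and Adam8 (-1.10, SE 0.13). Each was lower in 4 of 4 mice, and none of these 8 calls ended under any other normalization or without any 1 array. With the median in place of loess the median of all genes lay at -0.47, so lower calls in that setting say little.

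The erythroid list was called higher at day 10, with 4 of 25 genes higher and 0 lower, 18 higher when adjusted over the list alone. The mean was 0.45 in 4 of 4 mice (adjusted p = 1.60e-08; adjusted p = 0.573 with an estimated correlation), but -0.64 with the median in place of loess. Eraf, the chaperone of alpha-haemoglobin, was higher by 0.80 (SE 0.19), Hba-a1, whose probe is uncertain between alpha-globin copies, by 1.21 (SE 0.37, 3 of 3 mice), Bnip3l, which acts in mitochondrial clearance, by 0.74 (SE 0.21) and Sptb, erythroid spectrin, by 0.57 (SE 0.16); all 4 lay below 0 with the median. With mouse as a block the adjusted p of Hba-a1 was 0.0503. The heme synthesis and iron list had 6 of 18 genes higher, 9 higher when adjusted over the list alone. The mean was 0.35 in 4 of 4 mice (adjusted p = 0.000277; adjusted p = 0.465 with an estimated correlation), but -0.72 with the median. Its call also ended with the scanner software's log ratio, with scaling between arrays and in the Cy5 channel alone. Ftl1, ferritin light chain, was higher by 0.92 (SE 0.21), Glrx5 by 0.78 (SE 0.20), Blvrb, biliverdin reductase B, by 0.60 (SE 0.18) and Ppox, of heme synthesis, by 0.59 (SE 0.13), and these too lay below 0 with the median. Of these 8 genes, Sptb and Glrx5 then stayed above the median of all genes (-0.47). The spike-in probes, which hold no blood RNA, rose by 0.55 in the same comparison. Leaving out 1 array ended the calls of Eraf (mouse 305, day 0, adjusted p = 0.0560), Glrx5 (315, day 0, adjusted p = 0.0842), Sptb (5 arrays, adjusted p up to 0.0942), Bnip3l (5 arrays, up to 0.106), Hba-a1 (6 arrays, up to 0.188) and Blvrb (6 arrays, up to 0.155), with mouse 305 on day 0 among the arrays for each of the last 4.

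The MHC class I presentation list was lower at day 10, with 4 of 13 genes lower, 6 lower when adjusted over the list alone and a mean of -0.23, below 0 in 3 of 4 mice (adjusted p = 0.0277; adjusted p = 0.716 with an estimated correlation). The immunoproteasome genes Psmb9 (-0.45, SE 0.13), Psmb10 (-0.50, SE 0.15) and Psme2 (-0.39, SE 0.10) and the chaperone Canx (-0.39, SE 0.12) were lower, but each of these calls ended without any 1 of 3 to 7 arrays, with adjusted p up to 0.143. The cell cycle list had 4 of 24 genes higher and 2 lower, 9 and 4 when adjusted over the list alone. The mean was 0.15 in 4 of 4 mice (adjusted p = 0.0338; adjusted p = 0.646 with an estimated correlation). With the median in place of loess it lay level with the other genes (0.0012 above their mean). Mki67, a marker of dividing cells, was higher by 0.76 (SE 0.22) and the mitotic gene Birc5 by 0.46 (SE 0.12), at -0.39 and -0.57 with the median (-0.47 for all genes), while the replication genes Mcm4 (-0.37, SE 0.082) and Pcna (-0.30, SE 0.077) were lower. Pcna lay at 0.027 in the Cy5 channel alone, and the calls of Mki67, Birc5 and Pcna ended without any 1 of 4, 6 and 3 arrays, with adjusted p up to 0.0933. The MHC class I call ended without mouse 305 on day 0 (adjusted p = 0.0985) or 310 on day 10 (adjusted p = 0.0817), and the cell cycle call without 310 on day 0 (adjusted p = 0.0512) or 320 on day 10 (adjusted p = 0.0541). Both ended without background correction and with negative control spots as background, and the MHC class I call also with scaling between arrays, the scanner software's log ratio and the Cy5 channel alone. The inflammatory cytokine and NF-kB list, at -0.16 with an adjusted p of 0.0584, passed with mouse as a block (adjusted p = 0.0432).

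Among the highest genes of day 10, 7 lay between 1.14 and 1.36. They were Stbd1, Klf2, Aqp2, a water channel known from the kidney, Cox17, a copper chaperone of cytochrome oxidase, Fbxl19, Rhox4e and Oaz1, the ornithine decarboxylase antizyme. All but Stbd1 lay between -0.49 and -0.21 with the median in place of loess, with only Oaz1 under the median of all genes, and Aqp2, Fbxl19 and Oaz1 lay at -0.48, -0.67 and -0.44 in the Cy5 channel alone. The other probe of Klf2 gave -0.53 and that of Fbxl19 -0.072. Stbd1 rests largely on mouse 320 of day 10, at 3.51 against 0.55 to 0.66 in the other 3 mice, and without that array its change was 0.64. Its call (adjusted p = 0.0492) ended without any 1 of the day 0 arrays (adjusted p up to 0.150, without mouse 305). In all, 2131 genes differed between days 10 and 0 (limma, two-sided, adjusted p under 0.05), 760 higher and 1371 lower, of which 1915 had the same sign in every mouse measured and 56 changed at least 2-fold. With the median in place of loess 12 genes were higher and 7102 lower, and the median change of all genes was -0.47. Leaving out 1 array gave 846 genes (mouse 305, day 0), 1419 (310, day 0), 1222 (305, day 10), 1168 (315, day 10) or 1237 (320, day 10). The 5 lists shifted became 8 without 315 and 9 without 320 of day 0.

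At day 15 the neutrophil transcripts were again lower than at day 0. The mature neutrophil list had 10 of 18 genes lower, 15 lower when adjusted over the list alone. The mean was -0.74, below 0 in 4 of 4 mice (adjusted p = 4.22e-13; adjusted p = 0.465 with an estimated correlation). S100a9 changed by -2.10 (SE 0.27, adjusted p = 0.000318), S100a8 by -1.59 (SE 0.23), Cd300lf by -1.26 (SE 0.19, other probe -0.19), Retnlg, a resistin-like protein of granulocytes, by -1.22 (SE 0.17) and Adam8 by -1.17 (SE 0.13). Ifitm1 (-1.21, SE 0.32), Lrg1 (-1.16, SE 0.28) and Anxa1, annexin A1 (-1.15, SE 0.27), complete the 8 lowest with a symbol. The call of Ifitm1 ended without any 1 of 5 arrays (adjusted p up to 0.0831, without mouse 310 of day 0), and that of Lrg1 without 310 of day 0 (adjusted p = 0.0518). Il1b changed by -1.14 (SE 0.26, adjusted p = 0.011). The calls of Lrg1, Il1b, Ifitm1 and Anxa1 ended with the median in place of loess, and that of Retnlg with scaling between arrays.

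Further myeloid and signalling lists were lower at day 15. The myeloid suppressor list had 5 of 14 genes lower, also 5 when adjusted over the list alone. Its mean was -0.39 (adjusted p = 0.00332; adjusted p = 0.465 with an estimated correlation); Stat3, a cytokine-activated transcription factor, changed by -0.54 (SE 0.10). The phagocyte list had 6 of 18 lower and, adjusted over the list alone, 8 lower and 1 higher. Its mean was -0.23 (adjusted p = 0.000136; adjusted p = 0.465 with an estimated correlation); the oxidase subunit Ncf4 changed by -0.41 (SE 0.089). The inflammatory cytokine and NF-kB list had 4 of 16 lower, 5 when adjusted over the list alone. Its mean was -0.21 (adjusted p = 0.00352; adjusted p = 0.465 with an estimated correlation), including Socs3 (-0.80, SE 0.14) and Birc3 (-0.44, SE 0.083). The other probes of Stat3 and Birc3 lay at 0.0056 and 0.0085. The glycolysis and hypoxia list had 6 of 21 lower, 7 when adjusted over the list alone. Its mean was -0.22 (adjusted p = 0.000618; adjusted p = 0.465 with an estimated correlation), including the stress gene Ddit4 (-0.92, SE 0.13) and Slc16a3 (-0.80, SE 0.13). The monocyte list had 2 of 15 lower, 3 when adjusted over the list alone. Its mean was -0.25 (adjusted p = 0.042; adjusted p = 0.787 with an estimated correlation). Treml4 changed by -0.96 (SE 0.21) and the macrophage receptor Adgre1 by -0.52 (SE 0.15), the latter not past the threshold without any 1 of 6 arrays (adjusted p up to 0.154). The immediate early list had 3 of 16 lower and 1 higher, 6 and 1 when adjusted over the list alone. Its mean was -0.15 (adjusted p = 0.0471; adjusted p = 0.573 with an estimated correlation), and with mouse as a block its adjusted p was 0.0846. Junb changed by -0.80 (SE 0.15) and Klf6 by -0.36 (SE 0.084), against Klf2 at 0.81 (SE 0.23), whose other probe gave -0.66. Every list of this paragraph was below 0 in 4 of 4 mice. The monocyte call ended without mouse 305 (adjusted p = 0.0741) or 310 (0.0876) of day 0, or 305 (0.0556) or 315 (0.114) of day 15. The immediate early call ended without 310 (0.0740) or 320 (0.0867) of day 0, or 305 (0.0588), 310 (0.0501) or 315 (0.0658) of day 15. Klf6 was not past the threshold without 320 of day 15 (0.0508), nor Klf2 without any 1 of 6 arrays (up to 0.136). With the scanner software's log ratio all of these list calls but that of the glycolysis list ended, which ended in the Cy5 channel alone and with negative control spots as background.

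MHC class I, interferon, T cell and ribosomal lists were called lower at day 15. The MHC class I list had 4 of 13 genes lower, 8 when adjusted over the list alone. Its mean was -0.28 in 4 of 4 mice (adjusted p = 0.000197; adjusted p = 0.465 with an estimated correlation); the peptide-loading gene Tapbp changed by -0.49 (SE 0.094) and the proteasome activator Psme1 by -0.33 (SE 0.075). The ribosomal protein list had 10 of 27 lower and 1 higher, 14 and 1 when adjusted over the list alone. Its mean was -0.26, below 0 in 3 of 4 mice (adjusted p = 1.59e-05; adjusted p = 0.677 with an estimated correlation). The other probes of Tapbp and Il7r lay at 0.025 and 0.034. Rps4x changed by -0.88 (SE 0.15; its other probe gave 0.15) and Rpl6 by -0.54 (SE 0.090), against Rplp0 at 0.67 (SE 0.15), which lay at -0.86 with the median in place of loess. The T cell list had 5 of 20 lower, also 5 when adjusted over the list alone. Its mean was -0.15 in 4 of 4 mice (adjusted p = 0.0216; adjusted p = 0.741 with an estimated correlation), including Il7r (-0.56, SE 0.13) and the transcription factor Lef1 (-0.41, SE 0.11). The interferon stimulated list had 4 of 27 lower and 1 higher, 9 and 2 when adjusted over the list alone. Its mean was -0.15, below 0 in 3 of 4 mice (adjusted p = 0.0153; adjusted p = 0.741 with an estimated correlation), which became 0.12 with scaling between arrays. Rtp4 changed by -0.67 (SE 0.15) and Zbp1 by -0.60 (SE 0.14), against Isg15 at 0.97 (SE 0.24, higher in 3 of 4 mice), which lay at -0.38 with the median. The T cell call ended without mouse 315 of day 0 (adjusted p = 0.223) or 320 of day 15 (0.0640), and the interferon call without 320 of day 0 (0.168). The array of mouse 320 on day 0 correlated with the other day 0 arrays at a mean r across genes of 0.411 and with those of day 10 at 0.609. Lef1 was not past the threshold without any 1 of 4 arrays (up to 0.0975), Isg15 without 3 (up to 0.0728) and Zbp1 without 320 of day 15 (0.0522). With the scanner software's log ratio the MHC class I, T cell and interferon calls ended.

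The erythroid list at day 15 had 2 of 25 genes higher, 3 when adjusted over the list alone. Its mean was 0.27, above 0 in 3 of 4 mice (adjusted p = 0.00028; adjusted p = 0.732 with an estimated correlation), but -0.70 with the median in place of loess. Eraf was at 0.70 (SE 0.19) and Bnip3l at 0.74 (SE 0.21), below 0 with the median. The heme synthesis and iron list had 4 of 18 higher and, adjusted over the list alone, 5 higher and 1 lower. Its mean was 0.23 in 4 of 4 mice (adjusted p = 0.00641; adjusted p = 0.585 with an estimated correlation), but -0.72 with the median. Glrx5 was at 0.77 (SE 0.20) and Blvrb at 0.71 (SE 0.18), below 0 with the median, though Glrx5 stayed above that of all genes. The spike-in probes rose by 0.33 in this comparison. The erythroid call ended without mouse 305 of day 0 (adjusted p = 0.0725), the calls of the 4 genes without any 1 of 3 to 5 arrays (up to 0.160), and both list calls in the Cy5 channel alone. The 8 highest genes lay between 1.15 and 1.27: Slc22a8, an organic anion transporter, Aqp2, Fbxl19, Hbb-y, an embryonic globin whose probe is uncertain between globin copies, Marchf2, Ube2l6, Ghitm and Ube2s. Another probe of Fbxl19 lay at -0.023 and 1 of Marchf2 at -0.026. All 8 lay between -0.36 and -0.11 with the median, with only Ghitm under the median of all genes, and Ube2s was not past the threshold without any 1 of 4 arrays (up to 0.112). In all, 1172 genes differed from day 0 (limma, two-sided), 395 higher and 777 lower, 72 of them at least 2-fold and 1127 with the same sign in every mouse measured. With the median in place of loess 9 genes passed, all of them lower, while scaling between arrays gave 2420 higher and 2641 lower. Leaving out 1 array gave 662 (mouse 305, day 0) or 684 (320, day 15) genes. The median change of all genes with the median was -0.35.

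**Figure D2:**
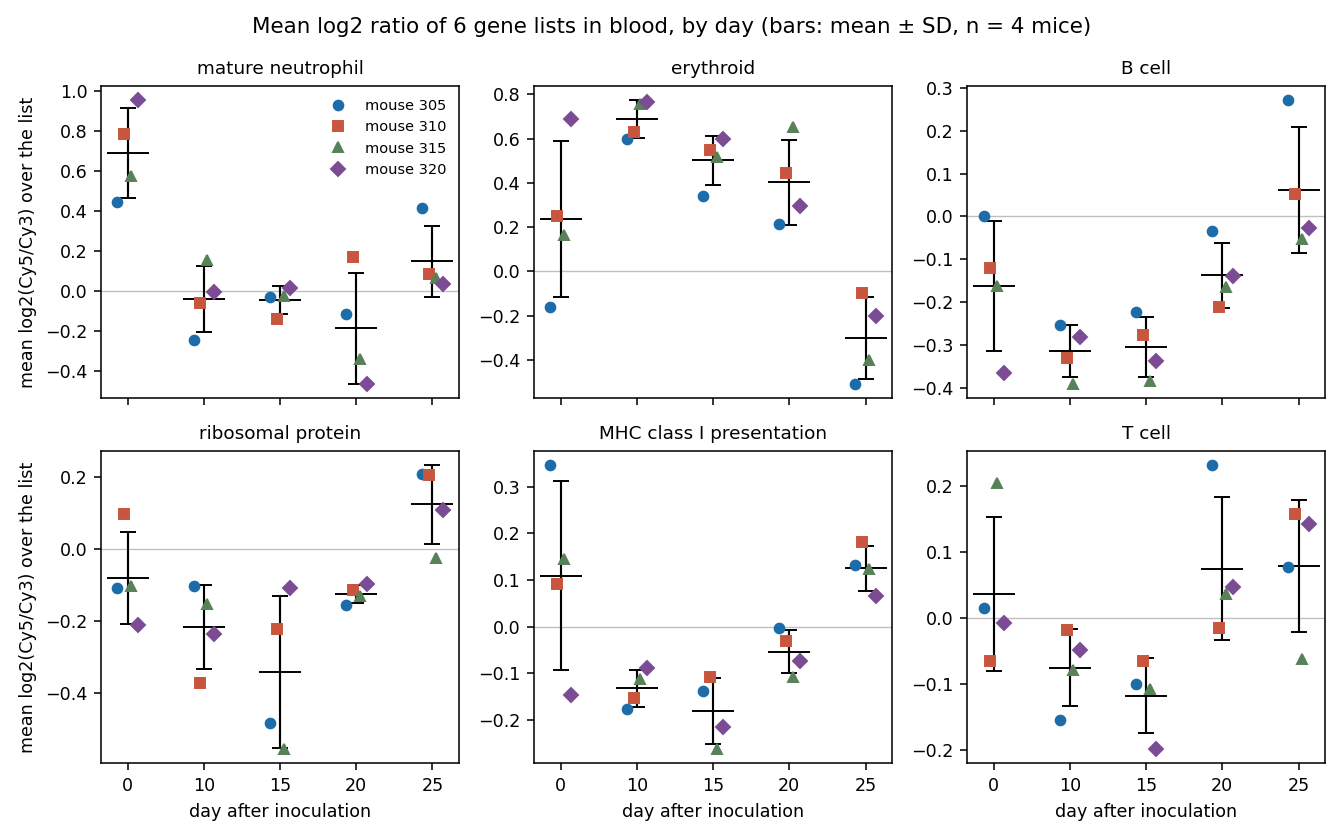
Mean log2(Cy5/Cy3) to the common reference (vertical axis) of the genes of 6 lists on each day after inoculation (horizontal axis), with 1 point per mouse and bars for the mean ± SD of 4 mice. The neutrophil list lay at 0.69 ± 0.23 on day 0 and -0.19 ± 0.28 on day 20, and the erythroid list at 0.24 ± 0.35 on day 0, 0.69 ± 0.086 on day 10 (below day 0 with the median in place of loess) and -0.30 ± 0.19 on day 25.

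At day 20 the neutrophil list showed its lowest mean against day 0, -0.88, below 0 in 4 of 4 mice (adjusted p = 5.84e-14; adjusted p = 0.465 with an estimated correlation). Of its 18 genes 12 were lower and 0 higher, and 17 were lower when adjusted over the list alone. S100a9 changed by -2.52 (SE 0.27) and S100a8 by -2.09 (SE 0.23), both with adjusted p = 0.00017. Lrg1 (-1.64, SE 0.28), Il1b (-1.41, SE 0.26), Cebpd (-1.38, SE 0.22), Wfdc21 (-1.32, SE 0.16), Hp (-1.30, SE 0.24) and Adam8 (-1.23, SE 0.13) were the others of the 8 lowest with a symbol, each lower in 4 of 4 mice. Of these 8, the call of S100a9 ended with scaling between arrays and those of Lrg1, Il1b, Cebpd, Hp and Adam8 with the median in place of loess. The myeloid suppressor list had 4 of 14 genes lower, 6 when adjusted over the list alone. Its mean was -0.38 in 4 of 4 mice (adjusted p = 0.0171; adjusted p = 0.566 with an estimated correlation); Clec4e, a pattern receptor of myeloid cells, changed by -0.79 (SE 0.15). The phagocyte list had 6 of 18 lower and 1 higher, 8 and 1 when adjusted over the list alone. Its mean was -0.20 in 4 of 4 mice (adjusted p = 0.00148; adjusted p = 0.573 with an estimated correlation). The Fc receptor Fcgr3 changed by -0.61 (SE 0.11) and the integrin Itgb2 by -0.49 (SE 0.095), against the complement gene C1qb at 0.56 (SE 0.15), which was not past the threshold without any 1 of 6 arrays (adjusted p up to 0.133). The glycolysis and hypoxia list had 3 of 21 lower and, adjusted over the list alone, 7 lower and 1 higher. Its mean was -0.21 in 4 of 4 mice (adjusted p = 0.000674; adjusted p = 0.465 with an estimated correlation), including Slc16a3 (-0.68, SE 0.13) and Ddit4 (-0.67, SE 0.13). The call of the myeloid suppressor list ended without mouse 305 of day 20 (adjusted p = 0.0749) and in the Cy5 channel alone, and that of the glycolysis list ended with scaling between arrays.

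In 3 other lists called at day 20 no single gene passed over all genes tested. The erythroid list had a mean of 0.16, above 0 in 3 of 4 mice (adjusted p = 0.014; adjusted p = 0.815 with an estimated correlation), with 0 genes past the threshold also when adjusted over the list alone, and lay at -0.49 with the median (-0.26 for all genes) and -0.071 with scaling between arrays. Eraf was at 0.64 (adjusted p = 0.067) and the blood group gene Kel at 0.53 (adjusted p = 0.152), which with mouse as a block became adjusted p = 0.0317 and 0.0355. The platelet list had a mean of -0.29, below 0 in 3 of 4 mice (adjusted p = 0.0255; adjusted p = 0.852 with an estimated correlation), with 0 genes past the threshold when adjusted over the list alone. Pf4, platelet factor 4, was at -0.73 (adjusted p = 0.0842) and the receptor gene Clec1b at -0.67 (adjusted p = 0.0769, and 0.0375 with the block). The list of liver and hepatoma transcripts had a mean of 0.16 in 4 of 4 mice (adjusted p = 0.0338; adjusted p = 0.677 with an estimated correlation), with 2 of 13 genes higher when adjusted over the list alone, and with the median lay at -0.017, above the -0.26 of all genes. Fgb, fibrinogen beta, was at 0.55 (adjusted p = 0.0705, and 0.0109 with the block) and Tat, tyrosine aminotransferase, at 0.44 (adjusted p = 0.0797, and 0.0336 with the block). At unadjusted p the fit gave 3757 genes under 0.05 over all genes tested at day 20. These calls ended without mouse 305 of day 0 (erythroid, adjusted p = 0.578, and liver, 0.0725), 315 of day 20 (erythroid, 0.154, and platelet, 0.159), 310 of day 20 (liver, 0.0691), 315 or 320 of day 0 (platelet, 0.0867 and 0.335) and 305 of day 20 (platelet, 0.113). All 3 ended with the scanner software's log ratio, with scaling between arrays, with negative control spots as background and in the Cy5 channel alone.

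The 8 highest genes of day 20 lay between 0.80 and 0.89: Best2, Carhsp1, Tmem107, Pced1a, Fbxl19, Olfr930, Cacna1a and Pabpc2. Other probes of Pced1a and Fbxl19 lay as low as -0.074 and -0.020, and that of Carhsp1 at 0.058. Fbxl19, Olfr930 and Pabpc2 lay at -0.051, -0.075 and -0.11 with the median in place of loess, above the median of all genes, and Tmem107 at -0.055 in the Cy5 channel alone. Their calls ended without mouse 315 of day 20 for all but Best2 and Carhsp1 (adjusted p from 0.0512 for Fbxl19 to 0.117 for Cacna1a). In all, 636 genes differed from day 0 (limma, two-sided), 231 higher and 405 lower, 15 of them at least 2-fold and 617 with the same sign in every mouse measured. With mouse as a block the count was 1469, with 833 higher and 636 lower. Scaling between arrays gave 160 higher and 470 lower genes, and with the median in place of loess 4 genes passed, all of them lower. The array of mouse 305 on day 20 correlated with the others of its day at a mean r across genes of 0.410, and without it the count was 2681. Leaving out 1 other array gave 226 (mouse 305, day 0), 243 (310, day 0), 364 (315, day 0), 1007 (320, day 0), 362 (310, day 20), 132 (315, day 20) or 207 (320, day 20). The median change of all genes with the median was -0.26.

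By day 25 a few single genes differed from day 0. Lower were S100a9 (-1.42, SE 0.27, in 3 of 4 mice), S100a8 (-1.19, SE 0.23), Prxl2a (-1.50, SE 0.27), Atg4a, of autophagy (-1.34, SE 0.24), Trim10, of the erythroid list (-1.28, SE 0.26), Dnajb2 (-1.04, SE 0.21), Wfdc21 (-1.02, SE 0.16), St3gal5, a ganglioside synthase (-0.89, SE 0.18), and Ube2f (-0.86, SE 0.17). Higher were Igh-VJ558, an immunoglobulin heavy chain probe uncertain between variable segments (0.73, SE 0.091, adjusted p = 0.00323), H2-Eb1, an MHC class II chain (0.50, SE 0.10), Dek (0.44, SE 0.082), Fcer2a, the B cell receptor for IgE (0.37, SE 0.067), Rps26 (0.34, SE 0.059) and Thap4 (0.26, SE 0.051). Other probes of Ube2f lay up to 0.045 and of Igh-VJ558 down to -0.045. In all, 31 genes passed (limma, two-sided), 7 higher and 24 lower, 8 of them at least 2-fold and 30 with the same sign in every mouse measured, out of 2661 at an unadjusted p under 0.05. Each of the 15 calls named here but that of Igh-VJ558 ended without at least 1 array, with adjusted p up to 0.200. The count became 185 without mouse 305, 2 without 310 and 1 without 320 of day 0, and 5 without 305, 1573 without 310, 11 without 315 and 4 without 320 of day 25. With mouse as a block it was 230, and 0 genes passed with the median in place of loess, where 459 had an unadjusted p under 0.05. Scaling between arrays gave 136 higher and 198 lower genes, and the Cy5 channel alone 998 and 785.

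Against day 0 the neutrophil, erythroid and heme lists were called lower at day 25, and the B cell, MHC class II and ribosomal lists higher. The neutrophil list had 2 of 18 genes lower, 14 when adjusted over the list alone. Its mean was -0.54 in 4 of 4 mice (adjusted p = 8.33e-11; adjusted p = 0.465 with an estimated correlation). The erythroid list had 1 of 25 lower, 18 when adjusted over the list alone. Its mean was -0.54 in 4 of 4 mice (adjusted p = 1.55e-11; adjusted p = 0.465 with an estimated correlation). The spike-in probes fell alike (-0.52), but in the Cy5 channel alone they lay at -0.010 and the erythroid list at -0.51. The carbonic anhydrase gene Car2 was at -1.06 (adjusted p = 0.0515, and 0.0236 with the block). The heme list had 0 of 18 past the threshold and 6 lower when adjusted over the list alone. Its mean was -0.34 in 4 of 4 mice (adjusted p = 7.60e-05; adjusted p = 0.465 with an estimated correlation). Blvrb was at -0.82 (adjusted p = 0.0635, and 0.0106 with the block). The B cell list had 1 of 19 higher, 8 when adjusted over the list alone. Its mean was 0.22 in 4 of 4 mice (adjusted p = 0.000575; adjusted p = 0.585 with an estimated correlation), and Cr2, complement receptor 2, was at 0.41 (adjusted p = 0.0667, and 0.0453 with the block), while its other probe gave -0.24. The MHC class II list had 1 of 10 higher, also 1 when adjusted over the list alone. Its mean was 0.20 in 4 of 4 mice (adjusted p = 0.00548; adjusted p = 0.677 with an estimated correlation), with Cd74, the invariant chain, at 0.25 (adjusted p = 0.264). The ribosomal list had 0 of 27 past the threshold and 4 higher when adjusted over the list alone. Its mean was 0.20 in 4 of 4 mice (adjusted p = 2.14e-06; adjusted p = 0.646 with an estimated correlation), but -0.097 with the median in place of loess. Rpl22 was at 0.42 (adjusted p = 0.0979; its other probe gave -0.11) and Rpl6 at 0.28 (adjusted p = 0.134). The calls of the B cell, MHC class II and ribosomal lists ended with the median and with array weights.

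A further 3 lists were called at day 25. The myeloid suppressor list had 0 of 14 genes past the threshold and, adjusted over the list alone, 4 lower and 1 higher. Its mean was -0.25 in 4 of 4 mice (adjusted p = 0.00967; adjusted p = 0.465 with an estimated correlation). Il1b was at -0.97 (adjusted p = 0.0984) and Clec4e at -0.64 (adjusted p = 0.0635, and 0.044 with the block). The interferon stimulated list had 0 of 27 past the threshold and 5 lower when adjusted over the list alone. Its mean was -0.22, below 0 in 3 of 4 mice (adjusted p = 0.00352; adjusted p = 0.677 with an estimated correlation). The antiviral genes Oasl2 and Oas3 were at -1.01 (adjusted p = 0.0945, and 0.0364 with the block) and -0.64 (adjusted p = 0.0984, and 0.0496 with the block). The eosinophil and basophil list had 0 of 11 past the threshold, also when adjusted over the list alone. Its mean was 0.10, above 0 in 3 of 4 mice (adjusted p = 0.0352; adjusted p = 0.677 with an estimated correlation), with Fcer1a at 0.21 (adjusted p = 0.151) and Il4 at 0.19 (adjusted p = 0.177). Without mouse 310 of day 25 the calls of the myeloid suppressor (adjusted p = 0.0553) and interferon lists (0.0691) ended, and the eosinophil and basophil call ended without mouse 305 (0.0647) or 315 (0.0777) of day 0 or 315 of day 25 (0.182).

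**Figure D3:**
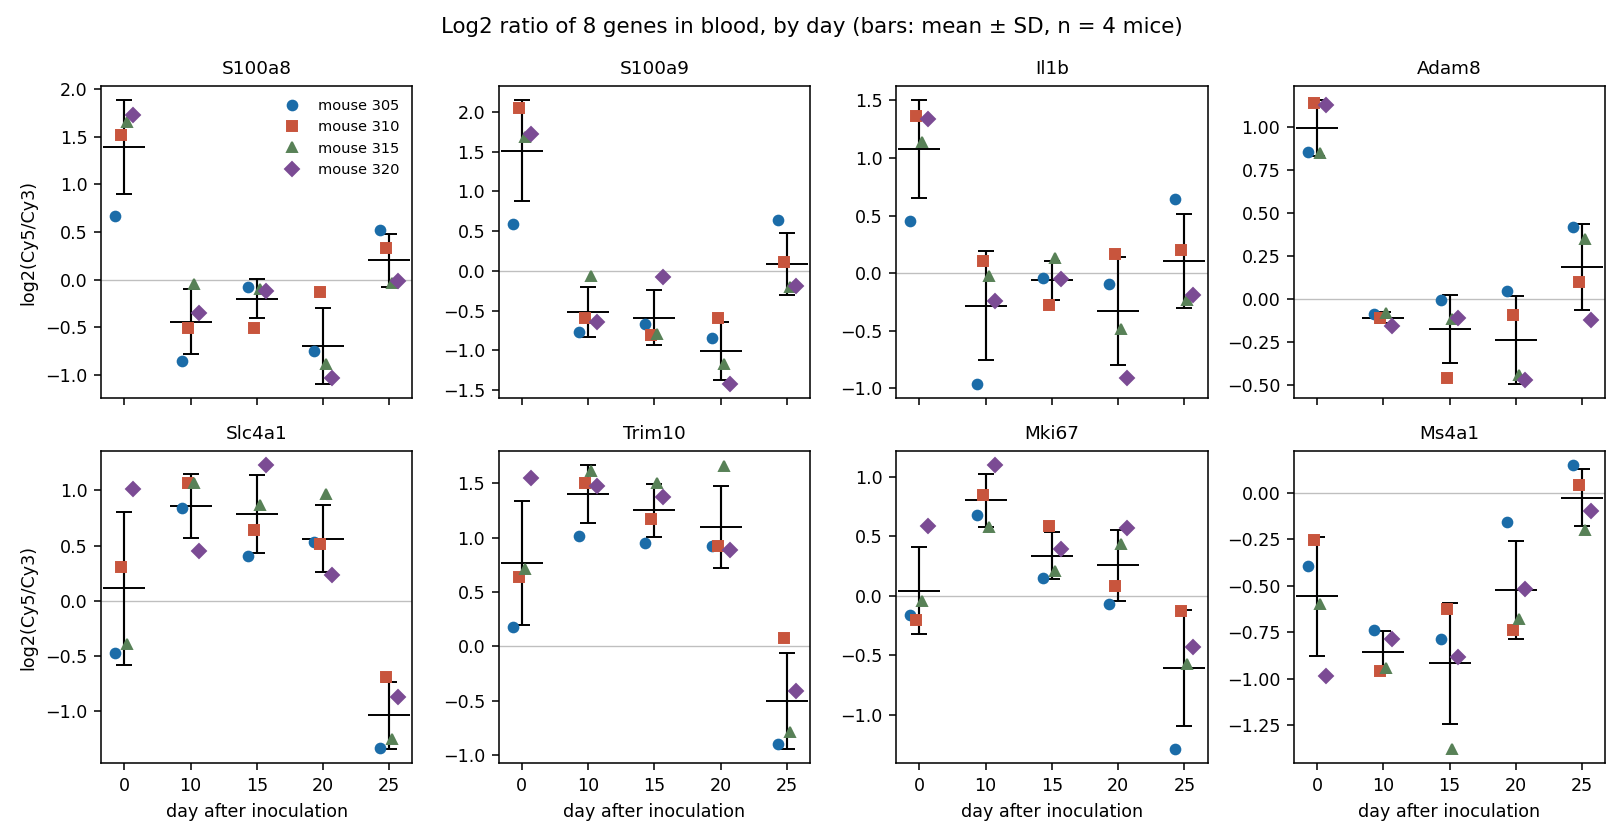
Log2(Cy5/Cy3) to the common reference (vertical axis) of S100a8, S100a9, Il1b, Adam8, Slc4a1, Trim10, Mki67 and Ms4a1 on each day after inoculation (horizontal axis), with 1 point per mouse and bars for the mean ± SD of 4 mice. S100a9 lay at 1.51 ± 0.63 on day 0 and -1.01 ± 0.36 on day 20, Slc4a1 at 0.86 ± 0.29 on day 10 and -1.04 ± 0.31 on day 25, and Ms4a1 at -0.85 ± 0.11 and -0.027 ± 0.15 on those days.

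Day 25 was set against day 10 to compare the last and the first bleed after inoculation. Red cell transcripts were lower at day 25. The erythroid list had 22 of 25 genes lower and 0 higher, 23 lower when adjusted over the list alone. Its mean was -0.99 in 4 of 4 mice (adjusted p = 5.86e-14; adjusted p = 0.465 with an estimated correlation), and -0.12 with the median in place of loess, where 3 of 4 mice were lower and the median of all genes was 0.46. The spike-in probes fell by as much (-1.07). Slc4a1, the anion exchanger of the red cell membrane, changed by -1.90 (SE 0.27, adjusted p = 0.000122), Trim10 by -1.90 (SE 0.26), Eraf by -1.71 (SE 0.19), the blood group gene Rhd by -1.67 (SE 0.23) and Car2 by -1.56 (SE 0.22). The heme list had 14 of 18 genes lower and 1 higher, 14 and 2 when adjusted over the list alone. Its mean was -0.69 in 4 of 4 mice (adjusted p = 2.07e-06; adjusted p = 0.465 with an estimated correlation), but 0.19 with the median, still under that of all genes. Glrx5 changed by -1.65 (SE 0.18), Blvrb by -1.43 (SE 0.18) and Ppox by -0.86 (SE 0.13), which lay at 0.24 with the median, still under that of all genes, against the iron transporter Slc11a2 at 0.32 (SE 0.088), whose probes ranged from -0.34 to 0.32. Also among the lowest genes were Cox17 (-1.98, SE 0.26), Atg4a (-1.96, SE 0.24), Apol11b (-1.96, SE 0.26), Klf2 (-1.92, SE 0.23; its other probe gave 0.87) and Apol10b (-1.85, SE 0.25). All of these lower genes were lower in 4 of 4 mice, and their calls ended both with the median and with scaling between arrays.

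The cell cycle list had 12 of 24 genes lower and 5 higher at day 25, also 12 and 5 when adjusted over the list alone. Its mean was -0.29 in 4 of 4 mice (adjusted p = 0.0313; adjusted p = 0.646 with an estimated correlation), and 0.42 with the median in place of loess, under the 0.46 of all genes. Lower were the mitotic genes Ube2c (-1.68, SE 0.21), Mki67 (-1.41, SE 0.22), Ccna2, cyclin A2 (-1.36, SE 0.21), and Nusap1 (-1.32, SE 0.20). The 5 higher members belong to DNA replication: Pcna (0.41, adjusted p = 0.000832), Mcm4 (0.35), Mcm6 (0.35), Mcm7 (0.32) and Mcm3 (0.20, adjusted p = 0.0495, and 0.0579 with mouse as a block). The call of the list ended without mouse 310 of day 25 (adjusted p = 0.0553) and that of Mcm3 without any 1 of 7 arrays (up to 0.185).

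B cell transcripts were higher at day 25 than at day 10. The B cell list had 11 of 19 genes higher and 0 lower, also 11 when adjusted over the list alone. Its mean was 0.37 in 4 of 4 mice (adjusted p = 0.00504; adjusted p = 0.677 with an estimated correlation). Higher were Ighm, the immunoglobulin M chain (0.99, SE 0.21), Ms4a1, which codes for CD20 (0.83, SE 0.16), Pou2af1, a B cell coactivator (0.77, SE 0.11), the chemokine receptor Cxcr5 (0.73, SE 0.13) and Fcrla (0.71, SE 0.11), along with Igh-VJ558 (0.97, SE 0.091, adjusted p = 3.16e-05). The probes of Ighm and Igh-VJ558 are uncertain between immunoglobulin copies. The MHC class II list had 4 of 10 genes higher, also 4 when adjusted over the list alone. Its mean was 0.28 in 4 of 4 mice (adjusted p = 0.0463; adjusted p = 0.754 with an estimated correlation): H2-DMb1 (0.55, SE 0.12), H2-Eb1 (0.47, SE 0.10), Cd74 (0.37, SE 0.11) and H2-Aa (0.36, SE 0.12), the last not past the threshold without any 1 of 3 arrays (adjusted p up to 0.129). The ribosomal list had 16 of 27 higher and 2 lower, 17 and 2 when adjusted over the list alone. Its mean was 0.34 in 4 of 4 mice (adjusted p = 0.000162; adjusted p = 0.716 with an estimated correlation). Rpl22 (0.81, SE 0.11), Rpl30 (0.69, SE 0.097), Rpl18 (0.56, SE 0.10) and Rpl6 (0.50, SE 0.090) were higher, against Rplp0 (-0.80, adjusted p = 0.000957) and Rpl28 (-0.34, adjusted p = 0.0326), which lay at 0.38 and 0.81 with the median (0.46 for all genes) and, for Rpl28, at 0.021 with the scanner software's log ratio. The call of Rpl28 ended without any 1 of 4 arrays (up to 0.182). The MHC class II call ended without mouse 310 (0.0925), 315 (0.0660) or 320 (0.0517) of day 10 or 305 (0.114) or 310 (0.0971) of day 25. The B cell and ribosomal calls ended with scaling between arrays and with array weights, and the MHC class II call under those and most other settings of background and scaling.

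The 8 highest genes of this comparison were Rps27 (1.11, SE 0.16), Ighm, Igh-VJ558, Ifi211, an interferon-inducible gene (0.94, SE 0.12), Ppig (0.93, SE 0.29), Chil3, a chitinase-like protein of myeloid cells (0.89, SE 0.22), Shisa5 (0.88, SE 0.19, with probes from -0.30 to 0.88) and Clk4, a splicing kinase (0.88, SE 0.098, with probes from -0.40 to 0.88), each in 4 of 4 mice. Ppig rests largely on mouse 310 of day 25, at 2.01 against 0.083 to 0.18 in the other 3 mice. Without that array its change was 0.46, and in the Cy5 channel alone it lay at -0.10. In all, 5241 genes differed between days 25 and 10 (limma, two-sided), 2993 higher and 2248 lower, of which 4743 had the same sign in every mouse measured. Of the 378 that changed at least 2-fold, 1 was higher and 377 lower. The split depended on the scaling. With the median in place of loess 7777 were higher and 123 lower, scaling between arrays gave 1567 and 1808, and the Cy5 channel alone 3198 and 1518.

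Days 15, 20 and 25 shared 1 scan date, while days 0 and 10 each had their own, so these days were also set against each other, a comparison chosen after seeing the data. Between days 25 and 15, 2038 genes were higher and 1400 lower. The erythroid list lay at -0.81, with 17 genes lower and 1 higher (adjusted p = 4.66e-11), the heme list at -0.57 (adjusted p = 1.85e-05), the ribosomal list at 0.46, with 17 genes higher (adjusted p = 3.85e-08), the B cell list at 0.37, with 9 higher (adjusted p = 0.00371), the MHC class II list at 0.32 and the MHC class I list at 0.31 (both adjusted p = 0.0149) and the glycolysis list at 0.20 (adjusted p = 0.0313). Between days 25 and 20, 1787 genes were higher and 2023 lower, with the erythroid list at -0.70 (adjusted p = 6.12e-10), the heme list at -0.46 (adjusted p = 0.000246), the cell cycle list at -0.24 (adjusted p = 0.0392), the neutrophil list at 0.34 and the eosinophil and basophil list at 0.16 (both adjusted p = 0.0461), the ribosomal list at 0.25 (adjusted p = 0.00296) and the glycolysis list at 0.19 (adjusted p = 0.0299). Between days 20 and 15, 21 genes were higher and 4 lower, with the ribosomal list at 0.22 (adjusted p = 1.29e-05), the B cell list at 0.17 (adjusted p = 0.012) and the platelet list at -0.22 (adjusted p = 0.0064). The adjusted p with an estimated correlation was 0.723 or more for every list here. Leaving out 1 array gave for days 25 and 15 a count of 2183 (mouse 320, day 15), 2165 (305, day 25) or 2021 (315, day 25), for days 25 and 20 a count of 2102 (315, day 20), 2428 (320, day 20), 2308 (305, day 25) or 2349 (315, day 25), and for days 20 and 15 between 2 and 12 genes except 1008 without mouse 305 of day 20. With mouse as a block the 25 genes of days 20 and 15 became 48.

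Of the genes followed at every day whatever their result, Il1b lay at 1.08 ± 0.43 (SD, n = 4) on day 0, -0.28 ± 0.48 on day 10, -0.060 ± 0.17 on day 15, -0.33 ± 0.47 on day 20 and 0.11 ± 0.41 on day 25. Between days 25 and 10 S100a8 was higher by 0.64 (SE 0.23, adjusted p = 0.0387; not past the threshold without any 1 of 5 arrays, up to 0.122), while S100a9 was at 0.61 (adjusted p = 0.0936) and Il1b at 0.39 (adjusted p = 0.262). Arg1, an enzyme of suppressive myeloid cells, was at 0.18, 0.055, 0.14 and 0.39 at days 10, 15, 20 and 25 against day 0, with adjusted p of 0.175 or more. The B cell gene Cd79a was at 0.11, 0.035, 0.20 and -0.017 (adjusted p of 0.112 or more), and at -0.12 between days 25 and 10, or 0.49 with the median in place of loess (0.46 for all genes). The T cell gene Cd3e was at 0.34, 0.15, 1.70 and -0.14 (adjusted p of 0.177 or more); the value of day 20 rests on mouse 305, whose ratio of 5.72 stands against 0.33 to 0.55 in the other 3 mice. Pf4 was at -0.49, -0.72, -0.73 and -0.22 (adjusted p of 0.0842 or more). Of the hepatoma transcripts, Afp, alpha-fetoprotein, was at -0.10, -0.059, -0.054 and 0.022 (adjusted p of 0.272 or more). Alb, albumin, was well above background on 0 arrays of days 0 and 15, 2 of day 10 and 1 each of days 20 and 25. The bounds of at least 1.09-fold at day 10 (adjusted p = 0.347) and 1.13-fold at day 20 (adjusted p = 0.261) went with no call. Day 25 was higher in 1 mouse and lower in 3 (adjusted p = 0.83). Alas2, the erythroid enzyme of heme synthesis, was not kept because its bright spot was non-uniform on 4 arrays.

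Of the 28 lists, 9 were called in no comparison. Their smallest adjusted p was 0.592 for granule proteins of immature granulocytes, 0.0813 for plasma cells, 0.43 for cytotoxic and NK cells, 0.191 for regulatory T cells and checkpoints, 0.784 for dendritic cells, 0.201 for haematopoietic progenitors, 0.17 for skin and muscle transcripts, 0.489 for oxidative phosphorylation and 0.145 for heat shock and unfolded protein. With the median in place of loess 5 of these lists gained calls, given here as shifts against the other genes. Oxidative phosphorylation lay at -0.72, -0.70 and -0.45 at days 10, 15 and 20, and skin and muscle transcripts at 0.53, 0.28 and 0.37 on those days and at -0.33 between days 25 and 10. Granule proteins lay at 0.36 at day 10 and -0.23 between days 25 and 10, plasma cells at 0.13 and progenitors at -0.11 at day 25. The 40 list calls over the 5 comparisons rest on camera's preset correlation. With an estimated correlation 0 of them passed, while the unadjusted p was under 0.05 in 2, 4, 1, 3 and 2 lists of the 5 comparisons, and fry, which tests a list without comparing it with other genes, passed 7, 8, 4, 4 and 10 lists. The median, the mean and the test of a list differed in sign in 17 of 140 cases, and 0 of those were called.

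The control spots differed between days as well. The 153 negative control spots of the day 0 slide had a Cy3 net intensity of 71.6 ± 14.4 (SD, n = 4 arrays), against means of -0.577, -0.644 and -1.17 on days 10, 15 and 20 and 14.5 on day 25. In Cy5 the means were 27.8, 4.11, 3.23, 2.90 and 4.77. The mean log2 ratio of 10 spike-in probes was -0.65 on day 0, -0.093 on day 10, -0.31 on day 15, -0.49 on day 20 and -1.16 on day 25. The erythroid list followed a similar course in the main setting. Against day 0, as means over mice, the spike-in probes changed by 0.55, 0.33, 0.15 and -0.52 and the erythroid list by 0.45, 0.25, 0.17 and -0.54, and between days 25 and 10 they changed by -1.07 and -0.99. Over the 20 arrays both means correlated at r = 0.932. In the Cy5 channel alone the erythroid list lay below the spike-in probes by -0.41, -0.44, -0.54 and -0.50 in the 4 comparisons with day 0, each in 4 of 4 mice, and by -0.067 (SE 0.17 over mice) between days 25 and 10. The spike-in probes had a median log2 intensity of 11.7, the erythroid genes 9.88 and all genes 8.16.

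Other genes named above had a weaker probe in the same direction: Sptb (0.076), Canx (-0.056) and Cox17 (0.28) at day 10, Lef1 (-0.017) at day 15, Fcgr3 (-0.17) at day 20, Dek (0.060) and Oas3 (-0.090) at day 25, and between days 25 and 10 H2-DMb1 (0.085), Ppig (0.15), Rpl22 (0.24), Ighm (0.31), Igh-VJ558 (0.050) and Cox17 (-0.42).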

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

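The comparison of the erythroid list with the spike-in probes, the use of negative control spots as background and the comparisons within days 15, 20 and 25 were chosen only after the results were seen. In 5 of 184 groups of 4 arrays, made from the 28 list means and 9 followed genes on each day where all 4 arrays had a value, 1 array lay far from the other 3, where chance gives about 1 in 20 groups, or 9.2. On day 25 the neutrophil list mean was 0.41 in mouse 305 and between 0.036 and 0.085 in the other mice. On day 20 the glycolysis and hypoxia list mean was 0.050 in mouse 310 and between -0.16 and -0.13 in the others. On day 15 S100a8 lay at -0.50 in mouse 310 and between -0.12 and -0.078 in the others, and Cd3e at 0.51 in mouse 310 and between 0.10 and 0.17 in the others. On day 20 Cd3e lay at 5.72 in mouse 305 and between 0.33 and 0.55 in the others, on an array that correlated with the rest of its day at a mean r across genes of 0.410.

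The change from day 0 differed between day 25 and day 10 for 6 lists, tested as day 25 against day 10 with camera. The adjusted p of the difference was 5.86e-14 for erythroid, 2.07e-06 for heme synthesis and iron, 0.000162 for ribosomal protein, 0.00504 for B cell, 0.0313 for cell cycle and 0.0463 for MHC class II genes, and 0 of the 6 passed with an estimated correlation. In spots that no comparison used, the negative controls of day 0 gave a Cy3 net intensity of 71.6, against -2.13 to 16.2 on the arrays of other days.

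Erythroid genes were lower at day 25 than at day 10, with a list mean of -0.99, and the 10 spike-in probes, which hold no blood RNA, fell by -1.07, so the list minus the spike-in probes was 0.081 (SE 0.19 over 4 mice). A shift shared with the spike-in controls, for example from labelling or from how bright spots were centred, may thus account for the whole fall. A difference between scan dates as the whole cause is argued against by days 25 and 15, which shared a scan date and differed by -0.81, with the spike-in probes at -0.85. The loess curve as the whole cause is argued against by the Cy5 channel alone, which uses no loess and gave -0.72 in 4 of 4 mice, but the spike-in probes fell there too (-0.65), and with the median in place of loess the list lay at -0.12 (SE 0.099 over genes) and the spike-in probes at 0.11, against a median of all genes of 0.46. There were 0 arrays of uninoculated mice after day 0, so tumour growth cannot be told apart from repeated bleeding of the same mice, nor either from the slide of each day, and all of these stay open beside the shared shift.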

How the results depend on the processing

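The settings with negative control spots as background and with both channels well above background on all 20 arrays were chosen after seeing the data. So were the fit without mouse 320 of day 0 and 305 of day 20 and the comparisons within days 15, 20 and 25. The first setting was redefined once. The neutrophil list kept its direction and its call in all 4 comparisons with day 0 under every setting but the estimated correlation, and the erythroid and heme lists did so for day 25 against day 0 and against day 10, with direction taken against the other genes (the heme list mean itself was 0.19 with the median in place of loess for day 25 against day 10). Aquantile normalization changed the call of 0 of 140 list results and 0 of 212 named gene results. It leaves the log ratios as they are, so this was fixed in advance and tests nothing. Camera with an estimated correlation ended 40 list calls. Under centring on the median 8 list results reversed, 6 lost and 21 gained a call, while 39 named gene results changed sign, of which 22 stayed on the same side of the median of all genes and 17 did not, and 73 lost a call. The median of all genes was then -0.47, -0.35, -0.26, -0.0073 and 0.46 in the 5 comparisons (days 10, 15, 20 and 25 against day 0 and day 25 against day 10), and -0.15, -0.15, -0.10, -0.043 and 0.15 with the scanner software's log ratio, against -0.022, -0.016, -0.021, -0.00067 and 0.034 in the report. Scaling between arrays ended 96 and the Cy5 channel alone 26 of the named gene calls. Under a fixed block for mouse 1 list and 2 named genes lost a call and 1 list and 12 named genes gained one, and it changed no other call. Leaving out 1 array ended 37 of the list calls and 228 of the named gene calls over all fits. The Cy5 signal was lowest on days 15 and 20. The cause of the differences below was not tested, except that fewer arrays or fewer genes enter some fits by construction.

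Counts of changed genes are given in the order of days 10, 15, 20 and 25 against day 0. Without background correction they were 6094, 6414, 2787 and 1968, with 9113 over the 5 days (F test) and 427 lower or higher at every day. With negative control spots as background they were 5613, 6243, 3149 and 2235, with 8779 over the 5 days, 650 at every day, and 6 and 4 lists at days 15 and 20. With the scanner software's log ratio, and identically with the series matrix, they were 4804, 6906, 1964 and 628, with 8847 over the 5 days, 135 at every day and 4 lists at each of days 15 and 20. In the Cy5 channel alone they were 3905, 7274, 3810 and 1783, with 9649 over the 5 days, 397 at every day, and 6 and 3 lists at days 15 and 20. Under the median in place of loess they were 7114, 9, 4 and 0 (limma, 459 at an unadjusted p under 0.05), with 9 lists at day 10, 7900 genes for day 25 against day 10 and 0 at every day (35 at an unadjusted p under 0.05). With scaling between arrays day 15 gave 5061 and day 25 gave 334, with 139 at every day, and day 25 against day 10 gave 3375 genes and 3 lists. An offset of 0 gave 2 at day 25 and 1 at every day.

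With mouse as a fixed block there were 1469 genes at day 20, 230 at day 25 and 22 at every day, and with mouse as a random block 97 at day 25 and 17 at every day. Array weights gave 2809, 81 and 0 genes at days 15, 20 and 25 (limma, 2142 at an unadjusted p under 0.05 at day 25), 2942 for day 25 against day 10, 7281 over the 5 days and 0 at every day (117 at an unadjusted p under 0.05). Only the arrays of the days compared gave 957, 738, 14 and 1, then 3310 for day 25 against day 10 and 1 at every day. At least 2-fold were 56, 72, 15 and 8, then 378, 119 of those over the 5 days and 3 at every day. With Cy5 well above background on all 20 arrays there were 109 at day 25 and 20 at every day, and with both channels so 121 and 20, with 3 lists at day 10. Without the filter on dim probes there were 414 at day 20, 10 at day 25, 5 at every day and 13 lists at day 10. Every probe tested gave 8 lists at day 10, and eBayes with trend and robust 56 genes at day 25. Without the arrays of mouse 320 on day 0 and mouse 305 on day 20 there were 2917 genes at day 20, 1 at day 25, 0 at every day (195 at an unadjusted p under 0.05) and 9 lists at day 10. Camera with an estimated correlation called 0 lists in each of the 5 comparisons, with 2, 4, 1, 3 and 2 at an unadjusted p under 0.05, and fry 8, 4 and 4 at days 15, 20 and 25 and 10 for day 25 against day 10.

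Leaving out 1 mouse or 1 array in turn, the count of genes ranged from 350 to 2841 at day 10, from 319 to 1598 at day 15, from 16 to 2681 at day 20, from 1 to 1573 at day 25, from 1940 to 6108 for day 25 against day 10, from 978 to 5925 over the 5 days and from 0 to 38 at every day (0 without mouse 320 of day 0, where 192 had an unadjusted p under 0.05). The count of lists ranged from 5 to 9 at day 10, from 11 to 13 at day 15, from 5 to 8 at day 20, from 7 to 11 at day 25 and from 5 to 8 for day 25 against day 10. Within 1 scan date it ranged from 0 to 1008 genes and from 1 to 8 lists for days 20 and 15, from 1064 to 5067 and from 4 to 9 for days 25 and 15, and from 32 to 4765 and from 3 to 9 for days 25 and 20. Single arrays with a large effect are named above.

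Signs changed as follows, with list values as the list mean minus that of the other genes, and gene values not set against the other genes, whose median is given above. At day 10 with the median in place of loess the erythroid list lay at -0.025, the heme list at -0.10, Klf2 at -0.36, Aqp2 at -0.40, Cox17 at -0.42, Fbxl19 at -0.42, Rhox4e at -0.21, Oaz1 at -0.49, Eraf at -0.64, Sptb at -0.13, Bnip3l at -0.85, Hba-a1 at -1.05, Ppox at -0.59, Ftl1 at -0.65, Glrx5 at -0.38, Blvrb at -0.93, Birc5 at -0.57 and Mki67 at -0.39. At day 15 the erythroid list lay at -0.18, the heme list at -0.20, oxidative phosphorylation at -0.70, Slc22a8 at -0.12, Aqp2 at -0.18, Fbxl19 at -0.21, Hbb-y at -0.20, Marchf2 at -0.31, Ube2l6 at -0.34, Ghitm at -0.36, Ube2s at -0.11, Eraf at -0.69, Bnip3l at -0.79, Glrx5 at -0.31, Blvrb at -0.71, Isg15 at -0.38, Rplp0 at -0.86 and Klf2 at -0.68. At day 20 it was the erythroid list at -0.14, Fbxl19 at -0.051, Olfr930 at -0.075 and Pabpc2 at -0.11, at day 25 the ribosomal list at -0.060, and for day 25 against day 10 granule proteins at -0.23, Cd79a at 0.49, Ppox at 0.24, Rpl28 at 0.81 and Rplp0 at 0.38. In the Cy5 channel alone Aqp2 lay at -0.48, Fbxl19 at -0.67, Oaz1 at -0.44, Bnip3l at -0.14, Hba-a1 at -0.53, Blvrb at -0.26 and Pcna at 0.027 at day 10, Tmem107 at -0.055 at day 20 and Ppig at -0.10 for day 25 against day 10. With scaling between arrays the interferon list lay at 0.13 at day 15 and the erythroid list at -0.041 at day 20. With every probe tested another probe of Klf2 gave -0.66 at day 15. With the scanner software's log ratio and the series matrix Rpl28 lay at 0.021 for day 25 against day 10.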

Other observations

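The comparison of the neutrophil list with the other white cell lists, the use of the spike-in probes and the tests with negative control spots as background were chosen only after the results were seen. Neutrophil genes were lower at days 10, 15 and 20 than at day 0, with a mean of -0.88 (SE 0.155 over genes) at day 20. With negative control spots as background, which lowers the raised Cy3 signal of the day 0 slide, the mean was -1.22 (SE 0.148), and the Cy5 channel alone, which leaves out the reference, gave -1.003, so neither background nor reference accounts for it as a whole. RNA of red cells diluting that of all white cells alike is argued against by the mean of 4 other white cell lists (B cell, T cell, cytotoxic and NK cell, monocyte), which the neutrophil list undercut by -0.82 on average and by -0.416, -0.632, -0.827 and -1.42 in the 4 mice. Against the reference of untreated blood the neutrophil list lay at 0.69 on day 0. It lay at -0.039, -0.045, -0.19 and 0.15 on days 10, 15, 20 and 25, so day 0 was furthest from that reference. A lower share of neutrophils later, or a higher level of their transcripts at the first bleed, are candidates that were not tested. The slide of each day also stays open.

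Genes higher at day 10 or day 15 than at day 0 were bright, with a median mean log2 intensity of 9.69 and 11.3 against 8.16 for all genes. With negative control spots as background 97.3% of these calls were again higher and past the threshold, and 86.8% lay above 0 in the Cy5 channel alone (81.6% at day 10 and 96.7% at day 15, with medians of 0.31 and 0.71), which argues against the day 0 background and the reference as whole causes. All but 1 of the 7 highest genes named for day 10 lay below 0 with the median in place of loess, as did all 8 of day 15. Only Oaz1 and Ghitm of these lay under the median of all genes (-0.47 and -0.35). The others lay above it by 0.011 (Ube2l6, day 15) to 0.26 (Rhox4e, day 10). Their size and sign thus depended on the centring, and their rank among genes was not compared. The spike-in probes, of a median log2 intensity of 11.7, also rose, by 0.55 and 0.33 (0.64 and 0.67 in the Cy5 channel alone), so a shift of bright spots shared with them stays open.

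Other splits of the 8 arrays of 2 days were counted with the same test, the other 12 arrays staying in the fit. Of the 35 splits of days 10 and 0, 1 gave as many changed genes as the real one (2131, highest other 937). For day 15 it was 1 (1172, highest other 377), and for day 25 against day 10 it was 1 (5241, highest other 901). These 3 counts were the highest of their 35 splits. For day 20 it was 2 (636, highest other 1578) and for day 25 against day 0 it was 4 (31, highest other 1384), so chance could not be excluded. Splits that call 1578 genes where the real one calls 636, or 1384 where it calls 31, point to a structure of the arrays within these days. Since mice pair the arrays, the real split was also set against the 8 splits that part all 4 mice. Their share cannot be under 0.125, so they cannot exclude chance. As many genes came from 1, 1, 1, 2 and 1 of these splits in the 5 comparisons, with highest others of 0, 0, 1, 215 and 458. The other splits put both arrays of at least 1 mouse on the same side, so differences between mice add to their counts.

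For gene lists, 31, 1, 20, 11 and 17 of the 35 splits gave as many shifted lists as the real 5, 13, 7, 9 and 6, with highest others of 13, 12, 12, 13 and 11. Only day 15 against day 0 exceeded all others, by 13 lists to 12. Among the 8 splits that part all mice it was 8, 1, 3, 2 and 2, with highest others of 10, 12, 10, 13 and 10, too few splits for a share under 0.05. The preset correlation thus calls lists in many arbitrary splits, and a count of shifted lists alone says little. When each mouse's 5 arrays were assigned to the days at random, 1 of 100 assignments, the real one, reached the F test's count (highest other 1275) and 1 of 100 the 9 genes lower at every day (highest other 0), so chance can be excluded for both.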
